A study of Mus musculus with 35 samples.

How the data were processed

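RNA was measured in the left lung lobe of 35 male mice. Per the labels' protocols, mice received either a control IgG or anti-Ly6G (clone 1A8), a monoclonal antibody against a neutrophil surface protein, each at 3 µg per g body weight, or DT (diphtheria toxin) at 10 ng per g, under the skin on 2 consecutive days. The DT mice carried MRP8-Cre and iDTR, an inducible receptor that makes Cre-expressing myeloid cells sensitive to the toxin, whereas all other mice were wild type. Lobes were perfused and frozen on the following day at a single clock time in the morning, which was ZT4 (4 hours after lights on) for mice of the normal facility and ZT16 for mice kept in cabinets with an inverted light cycle, per the labels' protocols. Time of day and housing therefore went together in every comparison. Each control and anti-Ly6G group held 7 mice, 3 from a July 2017 batch and 4 from a September 2017 batch. The DT groups, 4 mice at ZT4 and 3 at ZT16, came from an April 2018 batch without control mice, so DT, genotype and batch went together. The labels speak of 3 or 4 mice per group and batch, so each library was taken as a separate mouse and p-values measure spread between mice.

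RNA was amplified with a single-cell kit and made into Illumina libraries, per the labels' protocols. CASAVA 1.8.2, cutadapt, RSEM 1.2.20, kallisto 0.43.1 and the GRCm38 genome build are named, per the submitters' processing notes, without role or order. The values the authors deposited are normalised expression values per gene, handled here as a signal that is never negative. They are not whole numbers, hold 0 zeros among 22211 genes with a minimum of 0.0064, and their sums per library were close to each other but not equal, so they were treated neither as counts nor as CPM. How they were normalised, and whether they were adjusted for batch, is not given in the sources used here. The values themselves bear on the second point: the SD of the September minus July difference over its standard error was 0.525 across genes where unadjusted data of 2 batches give at least 1, and that of DT minus anti-Ly6G was 0.587, against 1.05 for DT minus control. Levels of DT mice were therefore not tested against those of control or anti-Ly6G mice. Values already aligned between batches can also make standard errors somewhat too small. Read depth is unknown and whole reads could not be recovered, so no counting interval is given. Between 15351 and 15802 genes per library reached a value of 1 (median 15553), and the 10 highest genes took 6.87% to 10.1% of the sum. No pair of libraries was identical, and the highest correlation between 2 libraries was 0.9931 against a median of 0.9881 within group and batch. Table columns named a group and batch but matched no single sample of the labels, so libraries are called by group, batch and table order (ZT4_control Sep#2), and these numbers pair nothing across groups.

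Genes at or above 1 in at least 3 libraries were kept (16786, with 5425 removed). limma 3.58.1 in R 4.3.3 was run with the trend option on log2(value + 0.5) of all 35 libraries, with a mean per group and a September against July term (28 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method over all genes kept with a threshold of 0.05, two-sided. Every adjusted p of a gene given below comes from this test. Fold changes are on the log2(value + 0.5) scale, which understates changes of low genes. The 9 contrasts were ZT16 minus ZT4 within each treatment, anti-Ly6G minus control at each time and over both, and 3 differences between time changes (interactions). Gene lists, 23 of pathways and 30 of cell types, were tested with camera in limma at a preset correlation of 0.01 and adjusted over the 53 lists within a contrast. Of their 1059 symbols, 1032 were in the table (6 under an older name) and 960 were tested. Camera was repeated with a correlation estimated per list. Only 1 of the 159 list calls held there, the xenobiotic list in anti-Ly6G mice over time, so list calls describe these samples and are weaker than the gene calls. Cell type lists are marker lists for whole tissue and do not identify cells.

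A neutrophil score, the mean log2 value of 22 mature neutrophil genes, was compared by exact two-sided permutation within batch, with Benjamini-Hochberg adjustment over 4 comparisons, the last of which (time in anti-Ly6G mice) was added later. Designs, lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names, per contrast, up to 8 genes with the largest rise and 8 with the largest fall among those passing with the same sign in each batch, a usual symbol and a level at or above the median of 4.397 (log2), or the 5 of smallest p where fewer than 5 pass; also all core clock genes, 7 neutrophil genes, and up to 4 members of smallest p per list. Some genes that meet this rule are not reported here. The planned test assumed counts only if the table held them, which it did not. Alternatives were pseudocounts of 0.1 and 1, no filter, a filter of 5 in 7 libraries, quantile and trimmed-mean scaling, library weights, robust variance, only the groups compared, no batch term, each batch alone and each library left out. A correction for transcript length and GC content, removal of pseudogenes and overlapping genes, 3 further settings for lists and DT mice against each batch alone were added after seeing the data.

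Gene positions are 1-based, from a GRCm38 annotation matched by identifier (16730 genes, 99.67%). Of symbols shared by several identifiers (29), list tests used the highest expressed. Exon overlaps were found with bedtools 2.31.1, figures drawn with matplotlib 3.10.9 under Python 3.11.15, and the seed was 1. The steps were tested on simulated data: of 100 genes each changed 1.5-fold and 2-fold, 78 and 95 were recovered in the comparison of time in control mice with 9 false calls, 75 and 95 for anti-Ly6G at ZT4 with 9, 61 and 84 for time in DT mice with 8, and 50 and 78 for the interaction of time with DT with 5, in each case among 16786 genes. A list planted in the simulated control comparison passed, as did 0 of 53 other lists. Simulated genes were drawn independently of each other, so these false calls do not show the error that correlation between real genes can bring.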

Results

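Messenger RNA of the lung was compared between 2 times of day in mice with and without neutrophil depletion, in 35 libraries of 6 groups. Control and anti-Ly6G groups held 7 mice at each time, and the DT groups 4 mice at ZT4 and 3 at ZT16. Values are the deposited normalised expression values, of unknown read depth, and differences are given as log2 change ± SE from limma unless a level is named. ZT16 mice lived under an inverted light cycle in other cabinets than ZT4 mice, so each time difference is also one of housing.

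The control mice show which lung transcripts differ between the rest phase (ZT4) and the active phase (ZT16). Single clock genes were among those that changed strongly. Cry1, a repressor of the clock, rose 2.84-fold from 15.2 ± 2.17 to 44.1 ± 4.42 (mean ± SD, n = 7 each). Nr1d1, which encodes the repressor REV-ERBα, fell from 309 ± 108 to 30.9 ± 16.6, and the lung chemokine gene Cxcl15 from 1320 ± 118 to 531 ± 44.4. The flavin monooxygenase gene Fmo2 rose 2.03-fold and the glutathione transferase gene Gsta3 1.97-fold.

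Across all genes, limma called 1517 of 16786 (9.04%), with 781 higher and 736 lower at ZT16 and a median absolute change of 0.33, and 1516 of them had one sign in both batches. Calls made on both batches pooled favour one sign, and over all genes the July and September time changes correlated at 0.336. Changes over 2-fold were seen in 33 genes. Cry1 (ENSMUSG00000020038, GRCm38 chromosome 10, 85131700 to 85185064) changed by 1.51 ± 0.084 (adjusted p = 2.2e-15), 1.41 in July and 1.58 in September. For Nr1d1 (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333) the change was -3.40 ± 0.31 (adjusted p = 1.2e-09), -4.63 in July and -2.47 in September. Cxcl15 (ENSMUSG00000029375, chromosome 5, 90794534 to 90803067) fell by 1.31 ± 0.071 (adjusted p = 1.9e-15). Other large rises were those of Akr1c14 (2.84-fold), a member of the aldo-keto reductase family, Cys1 (1.33), Per2 (1.29) and Sh3d21 (0.91). Other large falls were those of the clock output factor Dbp (-2.19), Acoxl (-1.33), Colq (-1.11), Lrg1 (-1.06) and the sodium channel gene Scn3a (-1.01). Exons of Nr1d1 share 263 bases with another gene, those of Dbp 539, Akr1c14 234 and Bhlhe41 1280. Without a stated use of strand their values are uncertain, and Akr1c14 also has close paralogs. The fall of Dbp did not pass in the September libraries alone (-1.39, adjusted p = 0.0766).

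Of 22 core clock genes, 6 rose, 3 fell and 13 did not pass in control mice, and 8 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.0168; adjusted p = 0.537 with an estimated correlation). Besides those named, Cry2 (0.33, adjusted p = 0.0239), Rora (0.37, adjusted p = 0.00409) and Nfil3 (0.70, adjusted p = 0.0223) rose and Bhlhe41 fell (-0.59, adjusted p = 0.0208). The call of Cry2 was lost without ZT4_control Sep#1 (0.27), ZT4_control Jul#1 (0.31) or ZT16_control Jul#3 (0.28). That of Nfil3 was lost without ZT16_control Sep#3 (0.58), ZT4_control Jul#2 (0.61) or Jul#3 (0.63), and it measured 1.24 in July and 0.30 in September. That of Bhlhe41 was lost without ZT4_control Jul#2 (-0.51) or Jul#3 (-0.48). Arntl, which encodes the activator BMAL1, differed by 0.80 in July and -0.96 in September (pooled -0.21, adjusted p = 0.716), and Nr1d2 by -1.25 and -0.06 (pooled -0.57, adjusted p = 0.0511). Among 22 clock output genes 5 rose and 1 fell, or 7 and 1 adjusted over the list alone, with Lonrf3 at 1.75 and the cell cycle kinase gene Wee1 at 0.80 (camera adjusted p = 2.2e-04; adjusted p = 0.256 with an estimated correlation).

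Of 31 genes of xenobiotic and antioxidant metabolism 9 rose at ZT16 and 2 fell, or 10 and 2 adjusted over the list alone, among them the carboxylesterase gene Ces1d (0.54) and the retinal dehydrogenase gene Aldh1a1 (0.46; camera adjusted p = 2.9e-05; adjusted p = 0.256 with an estimated correlation). Fatty acid oxidation genes went the other way, with 5 of 23 lower (6 adjusted over the list alone), including Acadl (-0.36) and the mitochondrial carnitine transferase gene Cpt1a (-0.46; camera adjusted p = 1.7e-04; adjusted p = 0.484 with an estimated correlation). Their median was 0.02 in July and -0.34 in September. Extracellular matrix genes held 6 falls and 1 rise among 32, or 9 and 2 adjusted over the list alone, with the crosslinking enzyme gene Loxl1 at -0.83, Fbn1 at -0.47 and the collagen gene Col1a1 at -0.42 (camera adjusted p = 0.00737; adjusted p = 0.567 with an estimated correlation).

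Lymphocyte markers were lower at ZT16 in control mice. Of 19 natural killer genes 7 fell and none rose, 11 adjusted over the list alone, with Klra7 at -0.77 ± 0.17 and the transcription factor gene Eomes at -0.80 ± 0.20 (camera adjusted p = 1.3e-06; adjusted p = 0.361 with an estimated correlation). Of 23 T cell genes 7 fell, 12 adjusted over the list alone, including Lck (-0.56; camera adjusted p = 1.3e-05; adjusted p = 0.484 with an estimated correlation). Of 20 B cell genes 5 fell, among them Cd37 (-0.64) and Ebf1 (-0.33), while Vpreb3 rose by 0.71, or 15 and 1 adjusted over the list alone (camera adjusted p = 2.6e-05; adjusted p = 0.567 with an estimated correlation). Of 21 alveolar type 2 (AT2) genes 7 fell, led by Cxcl15 and the calcium-binding protein gene S100g (-0.63 ± 0.08), and 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 4.6e-04; adjusted p = 0.537 with an estimated correlation). In all 22 lists passed in control mice, 5 upward and 17 downward, none of them with an estimated correlation, where the lowest adjusted p was 0.256.

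**Figure D1:**
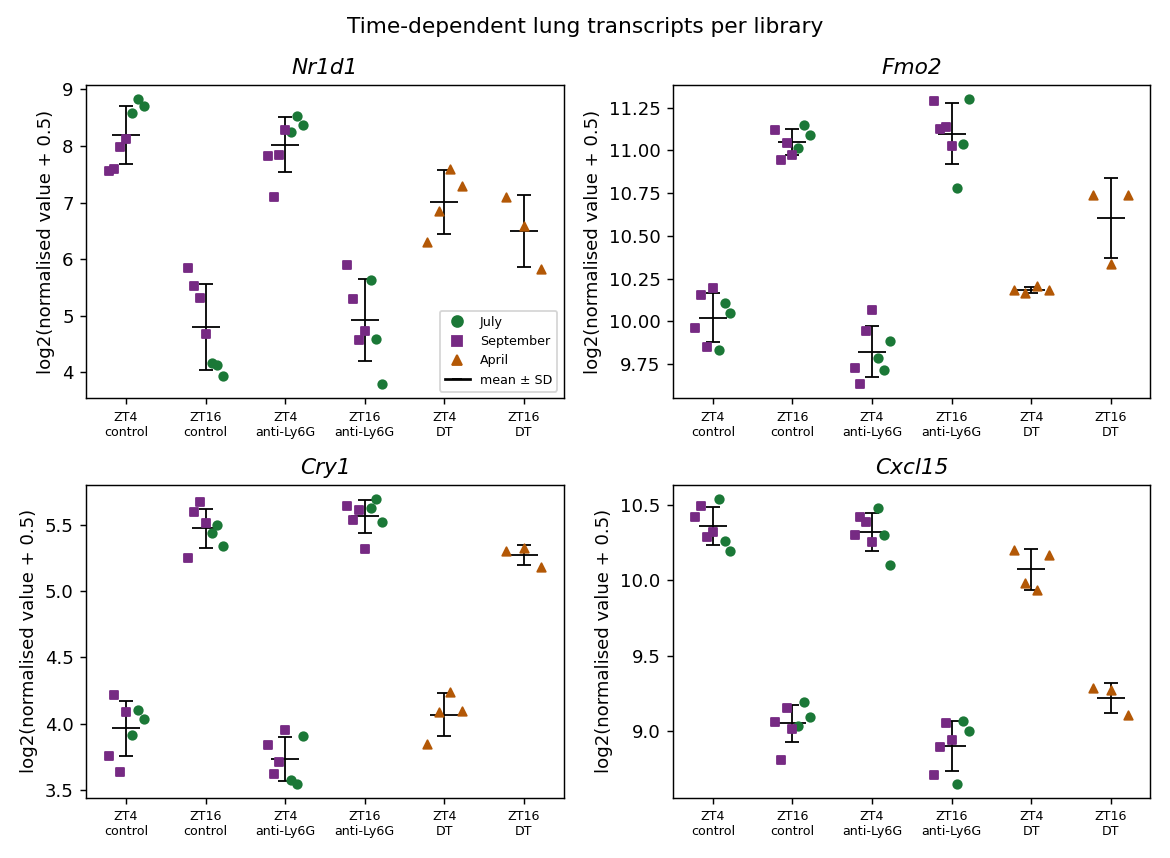
Expression of Nr1d1, Fmo2, Cry1 and Cxcl15 per library, as log2(normalised value + 0.5), in the 6 groups; circles are July, squares September and triangles April libraries, and bars show mean ± SD. Cry1 was higher and Cxcl15 lower at ZT16 in control, anti-Ly6G and DT mice, whereas Nr1d1 fell from 309 to 30.9 in control mice and had means of 135 and 95.7 in DT mice.

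Whether depletion removed neutrophil transcripts was read from the neutrophil score. It was lower after anti-Ly6G at both times, 2.77 ± 0.21 against 3.46 ± 0.88 at ZT4 and 2.48 ± 0.13 against 2.80 ± 0.24 at ZT16 (mean log2 ± SD, n = 7 each). The differences were -0.69 (exact permutation p = 0.0157, adjusted p = 0.0209) and -0.32 (exact permutation p = 0.00286, adjusted p = 0.0114), and in July alone -0.30 and -0.33, each with an exact p of 0.1, the smallest that 3 against 3 mice allow. In September alone they were -0.98 (exact p = 0.171) and -0.31 (exact p = 0.0571). The control group at ZT4 held a library, Sep#2, with a score of 5.29. Without it the ZT4 difference was -0.39, and without ZT4_antiLy6G Sep#1, Sep#3 or Sep#4 the exact p rose to 0.0614, 0.0843 and 0.103. The granule protein genes, made mainly by immature neutrophils, differed by -0.06 (exact p = 0.486) and 0.01 (exact p = 0.894), and Ly6g itself, the antibody's target and too low for the filter, by -0.61 (exact p = 0.13) and -0.01 (exact p = 0.943). In control mice the score was lower at ZT16 by 0.65 (exact permutation p = 0.0371, adjusted p = 0.0371; -0.15 in July, exact p = 0.3, and -1.03 in September, exact p = 0.143). The call depended on single libraries. It was lost without ZT4_control Sep#2 (-0.35), Jul#1 (-0.67) or Jul#3 (-0.68). It was also lost without ZT16_control Sep#1 (-0.67), Sep#2 (-0.66), Sep#3 (-0.58), Sep#4 (-0.58) or Jul#3 (-0.66). In anti-Ly6G mice the score was also lower at ZT16, by 0.288 (exact permutation p = 0.00857, adjusted p = 0.0171). With a library left out its exact permutation p was at most 0.0214. DT mice had scores of 2.70 ± 0.08 (n = 4) and 2.70 ± 0.38 (n = 3), and were not tested against other batches. Their depletion was therefore not checked here. Values that may have been aligned between batches cannot show it by a level like that of anti-Ly6G mice.

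**Figure D2:**
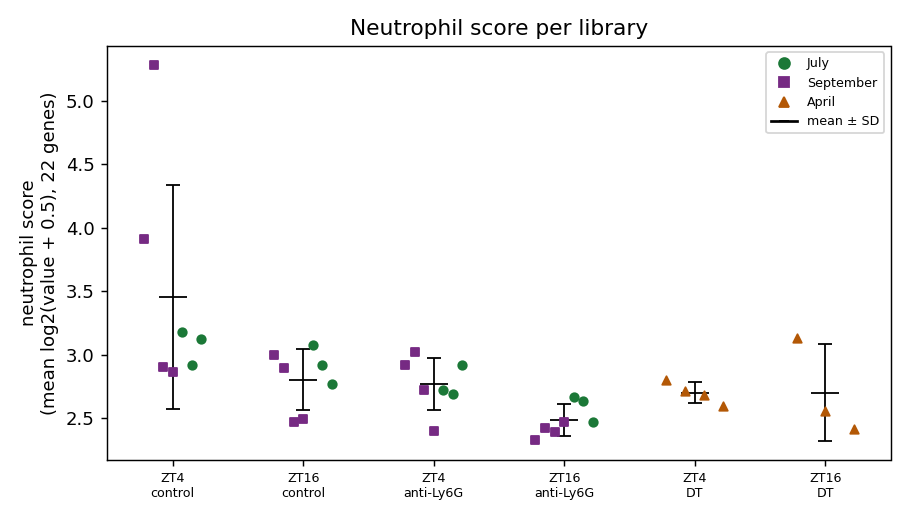
Neutrophil score of each library, the mean log2(value + 0.5) of 22 mature neutrophil genes, in the 6 groups; circles are July, squares September and triangles April libraries, and bars show mean ± SD. A ZT4 control library of the September batch lies at 5.29 and the 7 anti-Ly6G libraries at ZT16 lie between 2.32 and 2.67.

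No single gene was called after depletion with anti-Ly6G, and the values of neutrophil genes are given here as measured. At ZT4 the G-CSF receptor gene Csf3r (ENSMUSG00000028859, chromosome 4, 126024550 to 126044440) stood at 7.57 ± 1.55 against 28.7 ± 30.5 in controls (mean ± SD, n = 7 each), a log2 difference of -1.39 ± 0.329 (adjusted p = 0.34; -0.81 in July, -1.82 in September). The calprotectin genes S100a8 and S100a9, abundant in neutrophils, had differences of -1.18 and -1.59 at ZT4 and -1.14 and -1.08 at ZT16, none passing. S100a8 had levels of 8.14 ± 3.00 against 41.4 ± 69.9 at ZT4 and 4.38 ± 0.953 against 11.6 ± 6.17 at ZT16 (n = 7 each). Retnlg, Cxcr2 and Mmp9 differed by -0.99, -0.69 and -1.10 at ZT4 and by -0.52, -0.18 and -0.56 at ZT16, also not passing.

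No gene passed limma's threshold: 0 genes at ZT4 (1185 at unadjusted p under 0.05, lowest adjusted p = 0.34), 0 at ZT16 (701, lowest adjusted p = 0.682) and 0 over both times (902, lowest adjusted p = 0.27), where chance alone gives about 839. The genes of smallest p at ZT4 were Csf3r, Kif4 (0.66), Stap1 (0.60), Arhgap22 (0.39) and Lsm5 (0.36), and at ZT16 Dmd (-0.28), Cox10 (0.28), Gm4787 (-0.61), Iqcb1 (-0.32) and Hoxb2 (0.50). Over both times they were 5430405H02Rik (0.30), Csf3r (-1.08), Dmd (-0.20), Nlrp12 (-0.95) and Mmp9 (-0.83). Differences at the 2 times did not go together across genes (Pearson r = 0.03, Spearman rho = -0.0025, over genes, which are not independent replicates). Within a contrast, July and September differences correlated across genes at 0.109 for ZT4 and -0.029 for ZT16.

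Some gene lists passed at the preset correlation without a gene called over all genes. At ZT4, 23 of 53 lists passed, 8 upward and 15 downward, and at ZT16 11 did, 8 upward and 3 downward, none of them with an estimated correlation. The mature neutrophil list had a median of -0.70 at ZT4, with 14 of 22 genes lower adjusted over the list alone (camera adjusted p = 4.0e-12; adjusted p = 0.28 with an estimated correlation). Without ZT4_control Sep#2 that median was -0.41, and it was -0.19 in July and -1.0 in September. At ZT16 it was -0.29, with 0 genes adjusted over the list alone (camera adjusted p = 0.01; adjusted p = 0.939 with an estimated correlation). Natural killer genes had positive medians at both times, 0.18 at ZT4 and 0.14 at ZT16, with Klra4 (0.74) and Klrd1 (0.46) of smallest p at ZT4; adjusted over the list alone, 2 were higher at ZT4 and 0 at ZT16 (camera adjusted p = 5.4e-04 and 0.00375; adjusted p = 0.56 and 0.939 with an estimated correlation). The medians were 0.27 in July and 0.09 in September at ZT4, and 0.13 and 0.15 at ZT16. Natural killer genes were not alone in this. B cell genes also passed upward at ZT4 without ZT4_control Sep#2, with a median of 0.288 (camera adjusted p = 0.00866 at the preset correlation). Alveolar type 1 (AT1) genes had a median of -0.21 at ZT16, with 0 of 19 passing adjusted over the list alone (camera adjusted p = 9.9e-11; adjusted p = 0.864 with an estimated correlation). This lay in July (-0.40) more than in September (-0.05), with Pdpn at -0.51 and -0.05. Heart muscle genes, whose cells of origin were not tested, had a median of -0.29 at ZT4 (camera adjusted p = 4.2e-12, adjusted p = 0.3 with an estimated correlation). Adjusted over the list alone 8 of 21 were lower, among them Actn2 (-0.45) and Casq2 (-0.47). The median was -0.41 in July and -0.21 in September.

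The time difference of control mice was present in anti-Ly6G mice as well. Cry1 rose 3.54-fold, from 12.9 ± 1.53 to 46.9 ± 3.86, and Per2 3.42-fold, while Nr1d1 fell from 272 ± 78.9 to 33.3 ± 16.2 and Cxcl15 from 1280 ± 109 to 480 ± 52.8 (mean ± SD, n = 7 each). The chaperone genes Hspa8 and Hsph1 rose with time in these mice, by 1.10 ± 0.19 and 1.28 ± 0.31. Of the 1517 genes called in control mice 1492 (98.4%) had the same sign, and across all genes the 2 time changes correlated with r = 0.67 (rho = 0.62, over genes, which are not independent replicates).

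In anti-Ly6G mice limma called 3514 genes (20.9%), 1775 higher and 1739 lower at ZT16, 89 of them over 2-fold and 3508 with one sign in both batches. Over all genes the July and September time changes of these mice correlated at 0.516. Control and anti-Ly6G mice both called 610 genes higher, against 82.6 for independent lists, and 514 lower, against 76.2, and none in opposite directions, against 159. The interaction of time with anti-Ly6G called 0 genes in limma, with 1007 at unadjusted p under 0.05 and a lowest adjusted p of 0.812, so the larger count in anti-Ly6G mice is not shown to be a difference in any gene. Its genes of smallest p were Cox10 (0.38), Kdf1 (-0.42), Iqcb1 (-0.49), Apba1 (0.43) and Wsb1 (-0.37). Other large rises in anti-Ly6G mice were those of Hspa1b (1.75 ± 0.568, adjusted p = 0.0258), Fam107a (1.68), Cys1 (1.64) and Akr1c14 (1.35). Large falls were those of Dbp (-1.67), Acoxl (-1.40), the guanylate-binding protein gene Gbp6 (-1.36), Scn3a (-1.20), the integrin gene Itgb6 (-1.15) and Colq (-1.13). Hspa1b, which has the near-identical neighbour Hspa1a, lost its call without ZT4_antiLy6G Sep#1 (1.62) or Sep#2 (1.51), or ZT16_antiLy6G Sep#1 (1.63), Sep#3 (1.65) or Jul#2 (1.48). Gbp6 (ENSMUSG00000104713), whose exons share 1726 bases with another gene, is likewise uncertain. September libraries alone did not pass Hspa1b (1.55), Hsph1 (1.09) or Dbp (-1.23), nor did July libraries pass Gbp6 (-1.54).

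Xenobiotic and antioxidant genes rose in 14 of 31 cases with 1 fall, or 16 and 1 adjusted over the list alone, led by Gsta3 (1.13) and Fmo2 (1.28; camera adjusted p = 3.5e-10; adjusted p = 0.0184 with an estimated correlation). Their median was 0.38 in July and 0.14 in September. Core clock genes rose in 10 and fell in 3 of 22 cases, or 10 and 4 adjusted over the list alone, adding the output factors Tef (0.52) and Hlf (0.59) and Per3 (0.64) to the rises (camera adjusted p = 0.00287; adjusted p = 0.457 with an estimated correlation). Heat shock genes held 8 rises and 2 falls among 20, or 11 and 2 adjusted over the list alone, and the falls were the cold-inducible genes Rbm3 (-0.47) and Cirbp (-0.60; camera adjusted p = 0.00159; adjusted p = 0.727 with an estimated correlation). Of 20 B cell genes 15 fell and 1 rose, or 18 and 1 adjusted over the list alone, with the receptor gene Cd79b at -1.09 (camera adjusted p = 1.1e-05; adjusted p = 0.565 with an estimated correlation). Of 23 T cell genes 13 fell, 15 adjusted over the list alone (camera adjusted p = 1.3e-04; adjusted p = 0.55 with an estimated correlation), and of 19 natural killer genes 8 fell, 11 adjusted over the list alone, with Klrd1 at -0.83 (camera adjusted p = 2.1e-05; adjusted p = 0.457 with an estimated correlation). Interferon-stimulated genes held 8 falls and 1 rise among 29, or 17 and 1 adjusted over the list alone, with the chemokine gene Cxcl10 at -1.16 and Mx1 at -0.48 (camera adjusted p = 5.8e-05; adjusted p = 0.721 with an estimated correlation). Mesothelial markers fell in 11 of 16 cases, 13 adjusted over the list alone, with Gpm6a at -0.64 and Lrrn4 at -0.80 (camera adjusted p = 2.7e-05; adjusted p = 0.457 with an estimated correlation). In all 20 lists passed, 8 upward and 12 downward. For the interaction 12 lists passed with 0 genes called, none with an estimated correlation (lowest adjusted p = 0.164).

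DT mice differed between ZT4 and ZT16 largely in other genes. Cry1 rose 2.30-fold, from 16.3 ± 1.84 to 38.1 ± 2.02, and Cxcl15 fell from 1080 ± 102 to 597 ± 40.7 (mean ± SD, n = 4 at ZT4 and 3 at ZT16). Nr1d1 had levels of 135 ± 49.4 and 95.7 ± 39.7. Scgb3a1, which encodes a secretoglobin of secretory airway cells, rose 2.02-fold, and Aplnr, the apelin receptor gene of capillary endothelium, fell 2.33-fold. Mean levels of Aplnr also fell in control (68.3 to 46) and anti-Ly6G mice (79.8 to 49). The collagen-binding integrin gene Itga1 fell from 183 ± 30.4 to 80.6 ± 17.5. The neurotrophin receptor gene Ntrk2 fell from 50.2 ± 7.13 to 15.7 ± 2.41 and Glp1r, the GLP-1 receptor gene, from 46.2 ± 20.9 to 13.9 ± 2.78.

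Here limma called 2565 genes (15.3%), 889 higher and 1676 lower at ZT16, 95 of them over 2-fold. The 10 highest genes took 6.87% to 7.98% of the sum in ZT4_DT and 9.03% to 10.1% in ZT16_DT libraries, so composition of the libraries went with time here. Quantile normalization gave 1271 higher and 1183 lower, a share of 51.8% higher in place of 34.7%. The count fell to 1190 without ZT4_DT Apr#1, to 1559 without ZT16_DT Apr#1 and to 1537 without ZT16_DT Apr#2. Large rises were seen for the lactoferrin gene Ltf (1.69 ± 0.434, adjusted p = 0.0083), Retnla (1.47 ± 0.274), Bpifa1 (1.29 ± 0.407, adjusted p = 0.0295), Cry1 (2.30-fold), Per2 (1.03 ± 0.327, adjusted p = 0.0295), Scgb3a1 (1.01 ± 0.241) and Cys1 (0.99 ± 0.167). Among genes at or above the median level with a usual symbol, falls were largest for Ntrk2 (-1.65 ± 0.252, adjusted p = 4.6e-05), Glp1r (-1.61 ± 0.259, adjusted p = 8.7e-05; ENSMUSG00000024027, chromosome 17, 30901817 to 30940791), Slfn5 (-1.27), Plcb1 (-1.23), Nr4a1 (-1.22), Aplnr (-1.22), Itga1 (-1.19) and Colq (-1.18). Mean levels of Plcb1 also fell with time in control (37.9 to 20.3) and anti-Ly6G mice (39.3 to 22.2), as did those of Aplnr and Colq. The call of Ltf was lost without ZT4_DT Apr#1 (1.40) or ZT16_DT Apr#1 (1.43). Bpifa1 lost its call without ZT4_DT Apr#1 (1.06), ZT16_DT Apr#1 (1.16) or Apr#3 (1.25) or with the length and GC correction (1.15). Per2 lost its call without ZT4_DT Apr#1 (0.71), Apr#2 (1.03), ZT16_DT Apr#2 (0.95) or Apr#3 (1.01), and Nr4a1 without ZT4_DT Apr#1 (-1.05), Apr#2 (-1.14), ZT16_DT Apr#2 (-1.16) or Apr#3 (-1.05) or with robust variance. The exons of Slfn5 share 559 bases with another gene and those of Itga1 685. Changes of all genes went slightly with transcript length in DT mice (Spearman rho = -0.31, over genes), as against 0.16 in control and 0.15 in anti-Ly6G mice.

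General capillary endothelium markers fell in 16 of 24 cases and rose in none, 16 adjusted over the list alone (camera adjusted p = 5.9e-10, adjusted p = 0.102 with an estimated correlation). Among them were the cadherin gene Cdh5 (-0.88 ± 0.099), Bmp6 (-0.79), the sialomucin gene Emcn (-0.74) and Aplnr (-1.22). Emcn also fell in control (-0.48) and anti-Ly6G mice (-0.63), and mean levels of Aplnr fell there too. Angiogenesis and growth factor genes fell in 17 of 31, 20 adjusted over the list alone, with Hgf at -1.59 ± 0.20, Igfbp3 at -0.78 and the VEGF co-receptor gene Nrp1 at -0.63 (camera adjusted p = 1.5e-07; adjusted p = 0.102 with an estimated correlation). Markers of the Car4-positive capillaries fell in 7 of 18, 9 adjusted over the list alone, including the VEGF receptor gene Kdr (-0.67; camera adjusted p = 0.00129; adjusted p = 0.431 with an estimated correlation). AT2 genes fell in 12 of 21, 14 adjusted over the list alone (camera adjusted p = 7.6e-07, adjusted p = 0.413 with an estimated correlation). Among them were the fatty acid transporter gene Cd36 (-0.80), Cxcl15 (-0.85), Lpcat1 (-0.39) and the surfactant lipid transporter gene Abca3 (-0.51). Against control mice the DT change was lower for Cd36 (-0.54) but higher for Cxcl15 (0.46), which fell by 1.31 there. The AT2 list passed in the interaction of time with DT only after length and GC correction (-0.21, camera adjusted p = 0.0113). Of 26 fibroblast genes 10 fell and 2 rose, or 11 and 2 adjusted over the list alone, with the PDGF receptor gene Pdgfra at -0.72 (camera adjusted p = 0.0014; adjusted p = 0.431 with an estimated correlation). Extracellular matrix genes fell in 10 of 32, 13 adjusted over the list alone, including the basement membrane collagen gene Col4a1 (-0.79; camera adjusted p = 3.4e-04; adjusted p = 0.431 with an estimated correlation).

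Ciliated cell genes rose in 15 of 24 cases, 19 adjusted over the list alone, with Lrrc23 at 0.65 ± 0.13, Cfap126 at 0.65 and Ccdc153 at 0.52 (camera adjusted p = 1.3e-10; adjusted p = 0.198 with an estimated correlation). Club and goblet cell genes rose in 14 and fell in 1 of 24, or 19 and 1 adjusted over the list alone (camera adjusted p = 2.7e-10, adjusted p = 0.12 with an estimated correlation). Of smallest p were Ces1d (0.43), Retnla, Cckar (0.51) and Aldh1a1 (0.43). Ces1d (0.54) and Aldh1a1 also rose in control mice and belong to the xenobiotic list too. Retnla and Cckar rose more in DT than in control mice, by 1.70 and 0.62, and the list median in control mice was -0.09. Xenobiotic and antioxidant genes rose in 13 and fell in 1 of 31, or 16 and 1 adjusted over the list alone, with Gsta3 at 0.58 and Gsta4 at 0.60 (camera adjusted p = 3.7e-07; adjusted p = 0.102 with an estimated correlation). Core clock genes rose in 3 of 22 cases, among them Cry1 and Per2, also 3 adjusted over the list alone (camera adjusted p = 0.0173; adjusted p = 0.473 with an estimated correlation). Oxidative phosphorylation genes rose in 10 of 30, 11 adjusted over the list alone (median 0.14; camera adjusted p = 6.2e-05; adjusted p = 0.604 with an estimated correlation), and ribosomal protein genes in 6 of 33, 6 adjusted over the list alone (median 0.14; camera adjusted p = 7.3e-06; adjusted p = 0.697 with an estimated correlation). Both of the latter lists lost their call with the length and GC correction, with medians of 0.009 and 0.013. In all 16 lists passed, 8 in each direction.

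**Figure D3:**
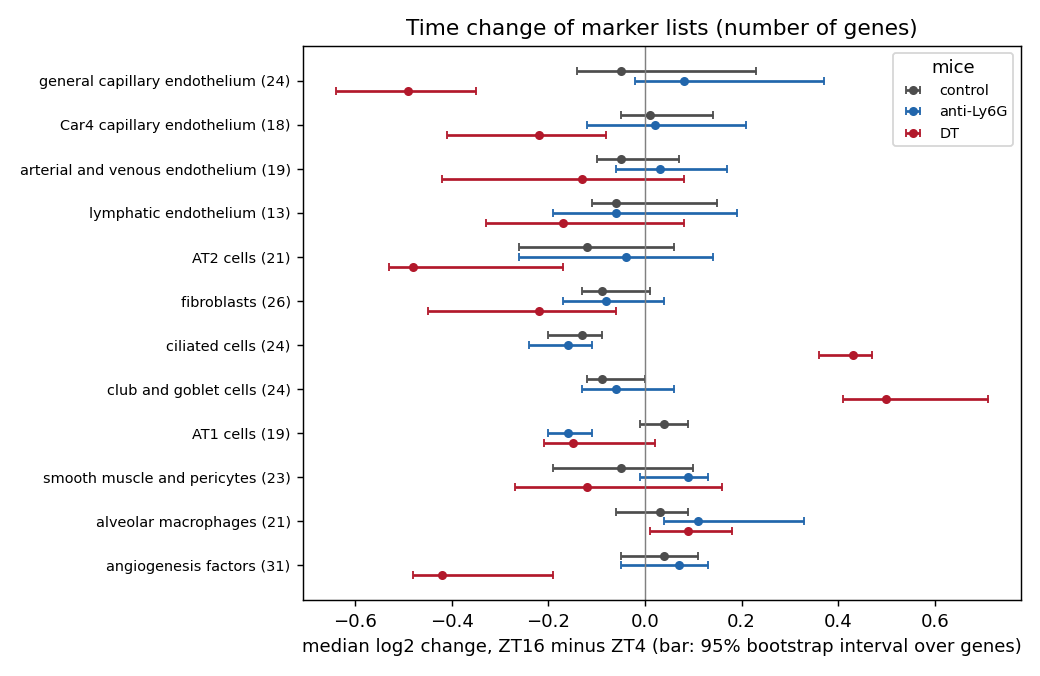
Median log2 change from ZT4 to ZT16 of the genes of 12 lists, with the number of genes, in control, anti-Ly6G and DT mice; bars are 95% bootstrap intervals over genes. These intervals leave out the spread between mice. In DT mice the general capillary list lies at -0.49 (-0.64 to -0.35) and the ciliated list at 0.43 (0.36 to 0.47), against -0.05 and -0.13 in control mice.

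Whether the time change itself differed in DT mice was tested as its difference from the other groups. The rhythm genes that fell in control mice without a call in DT mice differed: the change of Nr1d1 was higher in DT than in control mice by 2.89 ± 0.54 (adjusted p = 0.00114) and that of Dbp by 2.22 ± 0.647 (adjusted p = 0.0207), for DT changes of -0.51 ± 0.442 and 0.03 ± 0.53. The control changes were -4.63 and -3.26 in July and -2.47 and -1.39 in September, a spread these errors leave out. Against July controls alone the differences were 4.12 (adjusted p = 1.5e-04) and 3.29 (adjusted p = 0.00939), and against September controls alone 1.96 (adjusted p = 0.00823) and 1.42, the latter not passing (adjusted p = 0.16). Rora (-0.46) and Csnk1e (-0.25) also passed, but not with quantile normalization (-0.37 and -0.12). Nor did they pass against July controls alone (-0.40, adjusted p = 0.221, and -0.16, adjusted p = 0.32). Cry1 (-0.30, adjusted p = 0.158) gave no such difference against control mice. Glp1r differed by -1.75 ± 0.316 (adjusted p = 9.0e-04), having had levels of 23.7 ± 2.12 at ZT4 and 27.3 ± 8.69 at ZT16 in control mice (mean ± SD, n = 7 each).

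The interaction of time with DT called 2314 genes, 827 with a higher and 1487 with a lower time change in DT than in control mice, and that of time with depletion method, DT against anti-Ly6G, called 3202, 1249 higher and 1953 lower. Quantile normalization gave 1092 higher and 984 lower in the DT interaction (52.6% higher in place of 35.7%) and 1467 and 1436 in the method interaction (50.5% in place of 39.0%). The DT count was 1161 without ZT4_DT Apr#1, 1462 without ZT16_DT Apr#1 and 1488 without ZT16_DT Apr#2, and the method count 2121 without ZT4_DT Apr#1. Further genes with a higher change in DT than in control mice were Ltf (1.88), Retnla (1.70), the smooth muscle actin gene Actg2 (1.08), Scgb3a1 (1.06), the Notch target Hes1 (0.96) and Pigr (0.90), besides Bhlhe41 (1.06). A lower change was seen for Ntrk2 (-1.50), Slfn5 (-1.37), Itga1 (-1.32), Ston1 (-1.22), Pcdhac2 (-1.20), the transporter gene Abcb1a (-1.17) and Mbd1 (-1.16). Against the July libraries alone, which are fewer, the counts were 484 and 852, and against the September libraries alone 2243 and 3467. Ltf (1.44), Actg2 (0.79), Scgb3a1 (0.63) and Pigr (0.57) lost their calls against July controls, as did Rora (-0.40) and Csnk1e (-0.16). Against September controls Bhlhe41 (0.64) lost its call, besides Dbp. Pcdhac2 shares exons with the protocadherin cluster and is uncertain. Calls were lost without ZT4_DT Apr#1 for Dbp (1.76), Ltf (1.59), Scgb3a1 (0.82) and Bhlhe41 (0.89). The same held without ZT16_DT Apr#1 for Dbp (2.10), Ltf (1.61) and Bhlhe41 (0.92). Further losses came without ZT16_DT Apr#2 for Dbp (2.13) and Pigr (0.74), and without ZT16_DT Apr#3 for Scgb3a1 (0.96).

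Over all genes the time change of DT mice had a correlation near 0 with that of control mice (r = 0.06, rho = -0.0161) and of anti-Ly6G mice (r = 0.04; genes are not independent replicates). Among genes called in control mice r was 0.399 with a slope of 0.279, and among those called in anti-Ly6G mice r was 0.164. Among genes called in control mice 866 of 1517 (57.1%) had the same sign in DT mice, and 87 were called higher in both (41.4 for independent lists), 144 lower in both (73.5) and 96 in opposite directions (117). Of those called in anti-Ly6G mice 1676 of 3514 (47.7%) had the same sign in DT mice. Here 125 were called higher in both (94), 212 lower in both (174) and 338 in opposite directions (269). Called with one sign in all 3 kinds of mice were 74 genes higher (4.37 for independent lists) and 113 lower (7.61). The expected numbers take all 3 lists as independent, though control and anti-Ly6G mice shared 610 and 514 calls. This excess therefore does not by itself measure agreement with DT mice. Among the genes were Cry1, Gsta3, Ces1d and Cys1 upward and Cxcl15, Acoxl, Elovl1, Loxl1, Spon2 and Emcn downward.

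Ciliated genes had a higher change in DT than in control mice in 16 of 24 cases and a lower one in none, 19 adjusted over the list alone, with Pifo at 0.83 and Cfap126 at 0.88 (camera adjusted p = 6.8e-13; adjusted p = 0.195 with an estimated correlation). Capillary genes had a lower change in 12 of 24, 15 adjusted over the list alone, with the phosphatase gene Ptprb at -1.01 and the angiopoietin receptor gene Tek at -0.81 (camera adjusted p = 5.8e-08; adjusted p = 0.195 with an estimated correlation). Angiogenesis genes had a lower change in 14 of 31, 17 adjusted over the list alone (camera adjusted p = 2.1e-06; adjusted p = 0.195 with an estimated correlation). Against anti-Ly6G mice, the DT change was lower for Hspa1b (-2.96), Hspa1a (-2.73), Glp1r (-1.74), Ston1 (-1.57), Scube2 (-1.43), Krt80 (-1.43) and Cry1 (-0.62, adjusted p = 0.0034). It was higher for Nr1d1 (2.59, adjusted p = 0.0012), Retnla (2.22), Aldh1a2 (1.07, not passing against July mice alone) and Cirbp (1.06). The calls of Hspa1b and Hspa1a were lost without ZT4_DT Apr#4 (-2.67 and -2.43), ZT16_DT Apr#1 (-2.40 and -2.37) or ZT16_DT Apr#3 (-2.76 and -2.50). Both also lost it against September mice alone (-2.76 and -2.47). Hspa1b also lost its call without ZT4_antiLy6G Sep#2 (-2.72), ZT16_antiLy6G Sep#1 (-2.84) or ZT4_DT Apr#3 (-2.81) and with robust variance. Ciliated genes stood higher there too, in 17 of 24 cases (20 adjusted over the list alone; camera adjusted p = 4.2e-11; adjusted p = 0.218 with an estimated correlation), and mesothelial genes in 8 of 16 (13 adjusted over the list alone; camera adjusted p = 5.6e-06; adjusted p = 0.477 with an estimated correlation).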

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

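The tests of endothelial share and of overlapping genes and the random splits were chosen only after the results were seen, and those of length, of the single neutrophil library and of the clock were written down before their values were computed.

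Capillary genes such as Cdh5, Emcn and Aplnr were lower at ZT16 than at ZT4 in DT mice, with a list median of -0.49 (-0.64 to -0.35; adjusted p = 0.102 with an estimated correlation). Emcn also fell in control (-0.48) and anti-Ly6G mice (-0.63). Mean levels of Aplnr fell there too, from 68.3 to 46 and from 79.8 to 49. These 2 genes are thus not particular to DT mice, though the list medians were -0.05 in control and 0.08 in anti-Ly6G mice. Transcript length or GC content could produce such a shift of the list in DT mice, since changes of all genes went with length in them. After correction for both the median was -0.38 (-0.59 to -0.31), which argues against this as the whole cause. Both intervals are over genes of the list and leave out the spread between mice. A lower share of endothelium alone would leave epithelial lists alike, yet the AT2 median minus the ciliated one was -0.91. Both medians had been seen when this comparison was chosen, and the AT2 gene Cxcl15 also fell in control mice (-1.31). The value therefore describes these samples and is no independent test of that cause. A different mix of tissue in the material that gave RNA remains open, and batch, genotype and DT cannot be told apart here.

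The largest time changes in DT mice fell on genes such as Gm11175 (-4.48), Gm7334 (-3.86), Zfp708 (2.04) and Syn3 (2.24). Of the 10 genes changed over 4-fold 9 overlap another gene or are pseudogenes, 7.43 times the share of 12.1% among all genes (Fisher exact p = 4.9e-08). Reads shared between such genes may therefore account for these largest values. Among the 95 called with a change over 2-fold the share was 27.4% (Fisher exact p = 4.7e-05), against 6.06% of 33 in control mice, so these changes may be affected in part too. Among all genes called it was 8.73%, below that of all genes, so the count of 2565 is not explained this way.

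The mature neutrophil list had a median of -0.70 after anti-Ly6G at ZT4 (adjusted p = 0.28 with an estimated correlation), with Csf3r and S100a9 not passing, and a single control library, ZT4_control Sep#2, might account for it. Without it the list median was -0.41 and the score difference -0.39 (exact p = 0.0243), with 16 of 22 genes lower, which argues against this as the whole cause. The size of the difference still depended on that library.

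Of 150 groups of values of neutrophil and core clock genes (log2), 10 held an outlying sample, where chance gives about 1 in 20, or 7.5. Ly6g, the antibody's target, was 2.71 in ZT4_control Sep#2 against -0.64 to 0.02 in the others, and Retnlg, a resistin-like gene of neutrophils, 5.88 against 1.26 to 2.71. Ly6g was -0.85 in ZT4_DT Apr#4 against -0.44 to -0.40. The clock repressor gene Per1 was 5.19 in ZT4_antiLy6G Sep#1 against 6.96 to 7.50 and 5.95 in ZT16_antiLy6G Jul#1 against 7.26 to 7.71. Per2 was 8.08 in ZT16_control Sep#3 against 6.96 to 7.39, and Cry2 7.03 in ZT16_control Jul#3 against 6.67 to 6.80. Bhlhe40 was 5.56 in ZT16_antiLy6G Jul#3 against 5.94 to 6.03. Dbp was 4.32 in ZT4_antiLy6G Sep#2 against 5.52 to 6.39, and Csnk1e 6.66 in ZT4_control Sep#3 against 6.80 to 6.85.

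Time changes differed between groups in 2314 genes for DT against control and 3202 for DT against anti-Ly6G. For anti-Ly6G against control, list medians of the difference were 0.46 for mature neutrophil genes, 0.20 for alveolar macrophage, 0.15 for xenobiotic, 0.14 for fatty acid oxidation, 0.10 for cholesterol synthesis and 0.11 for efferocytosis genes. They were 0.21 for heart muscle, 0.18 for adipocyte and 0.14 for smooth muscle genes, and -0.09 for cell cycle, -0.20 for AT1 and -0.31 for mesothelial genes. Without ZT4_control Sep#2 the neutrophil value was 0.046, and it, the alveolar macrophage and the cell cycle list did not pass (0.157 and -0.087 for the latter). For DT against control they were 0.58 for ciliated, 0.53 for club and goblet, 0.78 for mature neutrophil, 0.43 for cell cycle, 0.41 for heart muscle, 0.40 for interferon-stimulated and 0.35 for mesothelial genes. They were 0.24 for oxidative phosphorylation, 0.14 for fatty acid oxidation and 0.13 for ribosomal protein genes. Without ZT4_control Sep#2 the neutrophil value of 0.78 became 0.481 (adjusted p = 0.0439). Lower values were -0.53 for general capillary, -0.42 for angiogenesis, -0.31 for Car4-positive capillary and -0.23 for efferocytosis genes. None of these lists passed with an estimated correlation. Lists of DT against anti-Ly6G were not scanned here.

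Random splits of the libraries asked only whether chance can be excluded, by how many called at least as many genes. Time in control mice (1517 genes) and in anti-Ly6G mice (3514) were reached by 1 of 100 splits, the real one, with highest others of 604 and 1265. Time in DT mice (2565) was reached by 1 of 35, with 1172 as highest other. The interactions with DT (2314) and method (3202) were reached by 1 of 100, with highest others of 18 and 46, in splits that mixed batches. Only the real split kept the April libraries together, so any difference of batch or genotype also sets it apart. The splits of these interactions are therefore no fair measure of chance and do not tell DT from batch or genotype. For anti-Ly6G, genes at unadjusted p under 0.05 were counted: 1185 at ZT4 were reached by 18 of 100, 701 at ZT16 by 52, 902 over both times by 30, and 1007 of the interaction by 21, so chance cannot be excluded there. The highest other splits had 2194, 2429, 2243 and 2178 such genes, several times the real number at ZT16. This may point to a structure of the samples other than treatment, or come from correlation between genes, and neither was tested.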

How the results depend on the processing

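No paired analysis was possible because table columns name a group and batch but match no single sample, so replicate numbers link nothing, and a fit with the replicate number as a replicate block could not be made. Tests on counts were not run since the table holds none. Apart from fewer samples, the cause of each change below was not tested.

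Clock and lung genes kept their calls under most settings. Of 231 named gene values 98 passed, and none of these 98 changed sign. Of them 4 lost their call with quantile normalization, 5 with length and GC correction and 3 with robust variance. Among 1526 values of these 98 with a library left out 81 lost the call, in 21 of the 98. In July libraries alone 11 of 44 lost it and in September libraries alone 10, with fewer samples. Genes called by time in control mice numbered 309 in July and 482 in September libraries alone, and those in anti-Ly6G mice 798 and 1467, with fewer samples in each. Leaving out a library gave 1136 to 1576 and 2857 to 3635. The contrasts of anti-Ly6G with control kept 0 genes under every setting.

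Genes called by time in DT mice numbered 1190 (without ZT4_DT Apr#1) to 2554 (without ZT4_DT Apr#4), with 1559 without ZT16_DT Apr#1 and 1537 without ZT16_DT Apr#2. The interaction of time with DT ran from 1161 (without ZT4_DT Apr#1) to 2633 (without ZT16_control Jul#3), with 1462 without ZT16_DT Apr#1 and 1488 without ZT16_DT Apr#2. The interaction of time with method ran from 2121 (without ZT4_DT Apr#1) to 3399 (without ZT16_antiLy6G Jul#2). Without pseudogenes and overlapping genes the counts were 2391, 2151 and 2887. With DT mice set against July libraries alone the interactions called 484 and 852 genes, and against September libraries alone 2243 and 3467, with fewer samples in each; this was added after seeing the data.

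Of 159 list calls 1 held with an estimated correlation, 145 without ZT4_control Sep#2, 142 with length and GC correction and 143 with quantile normalization. Ribosomal and oxidative phosphorylation lists lost their calls in DT mice with length and GC correction (0.013 and 0.009).

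The neutrophil score difference at ZT4 was -0.69, and -0.30 in July, -0.98 in September, -0.06 for granule genes and -0.61 for Ly6g alone; with a library left out it ran from -0.82 to -0.39 (without ZT4_control Sep#2). At ZT16 it was -0.32, and -0.33 in July, -0.31 in September and -0.01 for Ly6g alone, while granule genes had the reverse sign (0.01); with a library left out it ran from -0.37 to -0.27. By time in control mice it was -0.65, and -0.15 in July, -1.03 in September and -0.14 for granule genes, and with a library left out -0.78 to -0.35. By time in anti-Ly6G mice it was -0.29, and -0.19 in July, -0.36 in September, -0.06 for granule genes and -0.18 for Ly6g alone, and with a library left out -0.35 to -0.24.

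Correlation of time changes between control and anti-Ly6G mice was 0.77 with the stricter filter and 0.86 among genes called in either, against 0.67, and 0.63 to 0.68 with a library left out. Between control and DT mice it was 0.14 among genes called in either, against 0.06, and 0.02 to 0.10 with a library left out.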

Other observations

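A few genes changed with time of day differently in the July and September batches. Of control and anti-Ly6G mice together, 17 genes had a time change that differed between batches in limma, 10 higher and 7 lower in September, among 2018 at unadjusted p under 0.05. No list was tested on them, and the genes named here were chosen after their values were seen. Tcf21, a mesenchymal transcription factor gene, differed by 0.75 ± 0.12 (adjusted p = 0.011), Bcl6b, expressed in endothelium, by 0.93 ± 0.15 (adjusted p = 0.011) and Foxf1, a lung vascular regulator, by 0.53 (adjusted p = 0.0385). Lower in September were Itga7 (-0.55), Net1 (-0.35) and Gadd45g (-0.87). Of clock genes Nr1d2 differed by 1.07 ± 0.17 (adjusted p = 0.011) and Nr1d1 by 1.61 ± 0.32 (adjusted p = 0.0385), while Arntl (-1.45 ± 0.31, adjusted p = 0.058) and its relative Npas2 (-1.53 ± 0.37, adjusted p = 0.0914) did not pass.

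Single endothelial genes changed with time in mice in which their lists did not pass. In anti-Ly6G mice Lyve1, a hyaluronan receptor gene of lymphatic endothelium, rose by 1.07 ± 0.151 (0.53 in control mice) and Cd93 by 0.51, with medians of -0.06 for the lymphatic and 0.08 for the general capillary list. In control mice Ptprb, Calcrl and Tek rose by 0.47, 0.43 and 0.37 while Emcn fell by 0.48, so single markers of a cell type did not move as 1 group. Of 24 immediate early genes 5 fell with time in DT mice, 6 adjusted over the list alone, including Nr4a3 (-1.71), Atf3 (-0.97) and Klf4 (-0.74), and the list did not pass (camera adjusted p = 0.119; adjusted p = 0.697 with an estimated correlation).

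The test of a batch phase was written down after core clock values per batch and those of Fmo2 and Lrg1 had been seen, and the tests named in the first part of this section apply to the other ideas.

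Hypothesis: the July and September mice may have been sampled at somewhat different phases of their clocks. The difference between batches in the time change had a correlation of 0.91 between control and anti-Ly6G mice over 22 core clock genes, which had been seen before. Over 20 clock output genes it was 0.18, below the bound of 0.3 set for this idea and near the 0.23 of all genes, so the prediction failed. Among these genes Hif3a (-1.02 in control, 0.38 in anti-Ly6G mice) and Tsc22d3 (-0.51 and 0.21) differed in sign. Their batch differences had the largest standard errors of the output genes (0.53 and 0.44). The correlation depends on such uncertain values, so the failed prediction does not decide against the idea. A time course of Arntl and Nr1d1 across the day in each housing, in separate batches, would test it.

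Hypothesis: the mix of airway, alveolar and capillary tissue in the material that gave RNA could differ between the DT mice of the 2 times. The AT2 median minus the ciliated one (-0.91) and the capillary median after length and GC correction (-0.38) leave this open. Without that correction the AT2 list did not pass in the interaction of time with DT. Counting cells or staining Foxj1, Scgb1a1 and Pecam1 in sections of further DT and control mice of a single batch would test it.

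Hypothesis: the smaller difference of Nr1d1 and Dbp with time in DT mice may come from their batch or genotype and not from neutrophil loss. No gene was called in the limma interaction of time with anti-Ly6G (0 genes, 1007 at unadjusted p under 0.05), which does not show absence there. In July Nr1d1 changed by -3.71 after anti-Ly6G against -4.63 in control mice, and Dbp by -2.25 against -3.26. In September the values were -2.64 against -2.47 and -1.23 against -1.39. In the interaction of time with DT, Dbp lost its call without ZT4_DT Apr#1 (1.76), ZT16_DT Apr#1 or ZT16_DT Apr#2. It also lost it against September controls alone (1.42, limma adjusted p = 0.16). These values do not decide between the causes. DT given to mice without the receptor, in the same batch as mice with it, would test it.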
